A study of Arabidopsis thaliana with 8 samples.

How the data were processed

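RNA of roots and shoots from 8 samples was hybridised to Affymetrix ATH1 arrays, 1 array per sample with a biotin label. The deposited table holds 1 signal intensity per probe set and array on a linear scale. Per the submitters' processing notes, MAS5 and GCOS made these intensities; the scaling target, software versions and any filter are not given in the sources used here. From the values, the mean left after removing the lowest and highest 2% of the 22810 probe sets is 100.01 on every array, so the arrays were used as scaled. No detection calls were used. Groups and replicate numbers came from the sample titles.

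The 64 control probe sets were left out, leaving 22746. Probe sets were kept when their mean signal over the 8 arrays exceeded the 40th percentile (33.3), which left 13647. Values were tested as log2(signal + 16). In R 4.3.3 with limma 3.58.1, lmFit and eBayes with a trend fitted the 4 groups on all 8 arrays (4 residual and 4.34 prior degrees of freedom). Tests were two-sided, adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9.

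Names came only from the probe table supplied with the platform annotation, updated by gene identifier to TAIR10.1 gene records. It gives 1 gene for 13513 probe sets, several for 503 and none for 8730; 13436 of the first matched a record. Probe sets it does not list are unnamed here, not without a gene, so many well-studied nitrate genes were not analysed here by name. No coordinates are given.

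Before the data were examined, the tests, 16 gene lists and the rule for named genes were fixed. In roots and in shoots the rule took the 10 largest changes in each direction among called probe sets of 1 gene whose arrays did not overlap between treatments; where fewer than 5 passed, the 5 with the smallest p stand as values. For each list it took up to 4 called members, or 2 with the smallest p as values, and for the other comparisons the 5 largest changes in each direction. The rule also named 5 genes of nitrate uptake and reduction that the probe table does not list. Unnamed probe sets and genes in the additional observations were chosen after their values were seen.

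Lists were tested with camera on 1 probe set per gene, with a preset correlation of 0.01. Of the 16 lists, 14 had a tested gene; ammonium assimilation and trehalose 6-phosphate had none. Only 3 had at least 3 tested genes, and many tests therefore rest on a single gene.

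The fit was tested on simulated arrays for 13647 probe sets, 200 of them changed. With the same spread in both organs, as the fit assumes, 55% of 2-fold and 100% of 4-fold changes were recovered in roots, with 11 false among 166 calls, and 56% and 100% in shoots, with 14 false among 170. With a spread per organ, 69% and 100% were recovered in roots, with 2 false among 171 calls, and 60% and 100% in shoots, with 40 false among 200, above the nominal rate. With a spread per organ and a shift shared by arrays of the same number, 14% and 94% were recovered in roots and 9% and 89% in shoots, with no false calls among 108 and 98. The first and the last kind of noise were added after the other had shown the excess of false calls. The planned fit was kept.

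Alternatives covered the pseudocount (1 and 64), quantile normalization, the filter, the eBayes options, a replicate block, fits on fewer arrays, probe sets matching several genes, each array left out, stricter thresholds and other list tests. The lists were planned without a minimum size; a minimum of 3 tested genes, with a preset or an estimated correlation, was added after the coverage of the probe table was known.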

Results

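Gene expression was measured in roots and shoots of wild-type Arabidopsis thaliana Col-0, the common laboratory accession, after a short supply of nitrate at low concentration. Seedlings 10 days old were grown in liquid culture under constant light and received 250 µM potassium nitrate or, as the control, 250 µM potassium chloride (KCl) for 20 min. Each of the 4 groups (roots in KCl, roots in nitrate, shoots in KCl, shoots in nitrate) held 2 samples, giving 8 one-colour ATH1 arrays. The number of arrays limits the precision. The labels do not say whether the 2 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Median signals lay between 42.3 and 49.9 on the 8 arrays, and 13647 probe sets were tested. Of these, 7253 matched 1 gene in the probe table used here, and the others are unnamed.

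The arrays also differed by replicate number. In shoots ICL, which encodes isocitrate lyase of the glyoxylate cycle, had signals of 3049 (KCl) and 2572 (nitrate) on the arrays numbered 1, against 63.2 and 111 on those numbered 2. The plastid gene psbH ran the other way, with 354 and 314 against 1080.4 and 1115. The log2 difference between the 2 samples of a group had an SD over probe sets of 0.50 and 0.47 in shoots, and of 0.30 and 0.29 in roots.

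**Figure D1:**
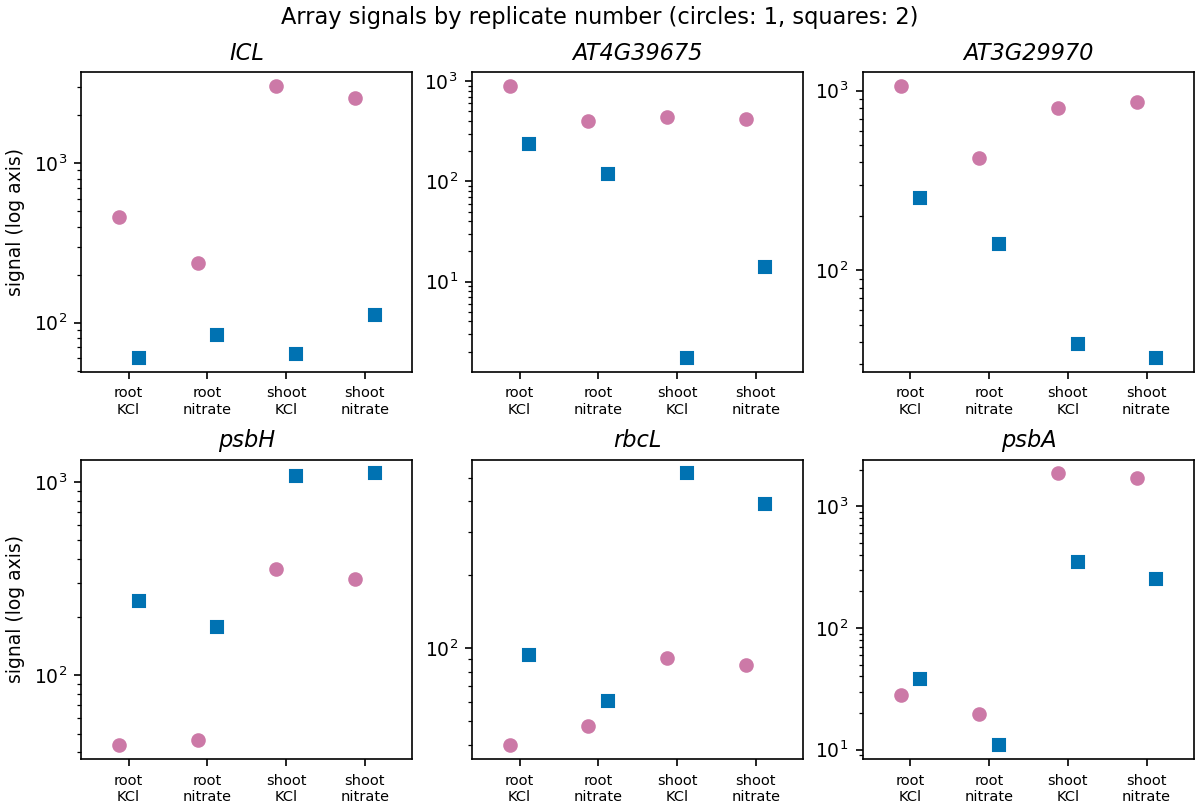
Signal on each of the 8 arrays (log axis) of 6 genes that differed by replicate number, with groups along the x axis, circles for replicate 1 and squares for replicate 2. ICL was higher on the array numbered 1 in all 4 groups, and psbH was higher on the array numbered 2 in all 4 groups.

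Nitrate against KCl in roots asked which transcripts respond to nitrate within 20 min. In the planned fit 141 probe sets rose and 14 fell, and with only the root arrays in the fit 223 rose and 56 fell. With a replicate block within each organ 322 rose and 195 fell, so the balance of rises and falls depended on the fit. PGM (AT1G78050), annotated as a phosphoglycerate/bisphosphoglycerate mutase, rose from a signal of 63.0 ± 3.57 to 1519 ± 425 (SD, n = 2 each). PGD3 (AT5G41670) and PGD1 (AT1G64190), which encode 6-phosphogluconate dehydrogenases of the oxidative pentose phosphate pathway, rose from 238 ± 12.3 to 1903 ± 265 and from 527 ± 58.7 to 3107 ± 175 (SD, n = 2 each). HHO2 (AT1G68670) and HHO3 (AT1G25550), GARP transcription factors known to respond to nitrate, rose from 78.9 ± 3.11 to 476 ± 86.8 and from 109 ± 4.25 to 568 ± 8.99 (SD, n = 2 each).

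On the log2(signal + 16) scale, which understates the change of transcripts of low signal, PGM rose by 4.25 ± 0.39 (SE; limma, adjusted p = 0.0016) and PGD3 by 2.91 ± 0.19 (adjusted p = 0.00043). AT2G48080 rose by 3.82 ± 0.19 (limma, adjusted p = 0.000112), from 47.2 ± 5.09 to 872 ± 29.9. AT1G80380, which encodes glycerate kinase of photorespiration, rose by 3.19 ± 0.19 (adjusted p = 0.000278). The 10 largest rises among called probe sets matching 1 gene also included AT3G07350 (3.61), AT5G10210 (3.51), AT3G50900 (3.04), AT5G09800 (3.04), AT4G36010 (2.93) and AT4G32950 (2.75). At a pseudocount of 1 AT5G10210 rose by 6.44, from a signal of 1.06 ± 0.08 in KCl. AT3G50900 was close to the threshold (limma, adjusted p = 0.0497) and missed it under 13 of 21 alternatives, with an adjusted p of up to 0.482; AT5G09800 missed it under 7 of 21.

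The falls were smaller. AT4G17670 fell by 1.57 ± 0.19 (SE; limma, adjusted p = 0.0056), from a mean signal of 602 to 191.5 ± 7.61 (SD, n = 2). The transcription factor gene tny (TINY, of the AP2/ERF family) fell by 1.19 ± 0.19 (adjusted p = 0.0242), from a mean signal of 319 to 132 ± 30.1. The threshold was missed by tny under 8 of 21 alternatives and by AT4G17670 under 4. The other 7 named falls ranged from AT2G40230 (log2 change of -1.34) through AT3G16800 (-1.23), AT4G18630 (-1.15), AT1G07870 (-1.02), SGP1 (-0.94) and AT1G33260 (-0.90) to AT1G27210 (-0.86). Among these, SGP1 and AT1G27210 missed the threshold under 11 of 21 alternatives, AT1G33260 under 10, AT1G07870 under 9, AT3G16800 and AT4G18630 under 8 of 20, and AT2G40230 under 6 of 20. Among probe sets with no gene in the table, the largest rises were 4.82 and 4.57 and the largest falls -1.57 and -1.33.

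Of 155 called probe sets, 145 changed at least 2-fold, and 769 had an unadjusted p under 0.05. The count rests on all 4 root arrays: it was 46 without the first KCl array, 48 without the second, 32 without the first nitrate array and 58 without the second, and at most 1 of these calls was a fall. With only the root arrays in the fit it was 279.

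**Figure D2:**
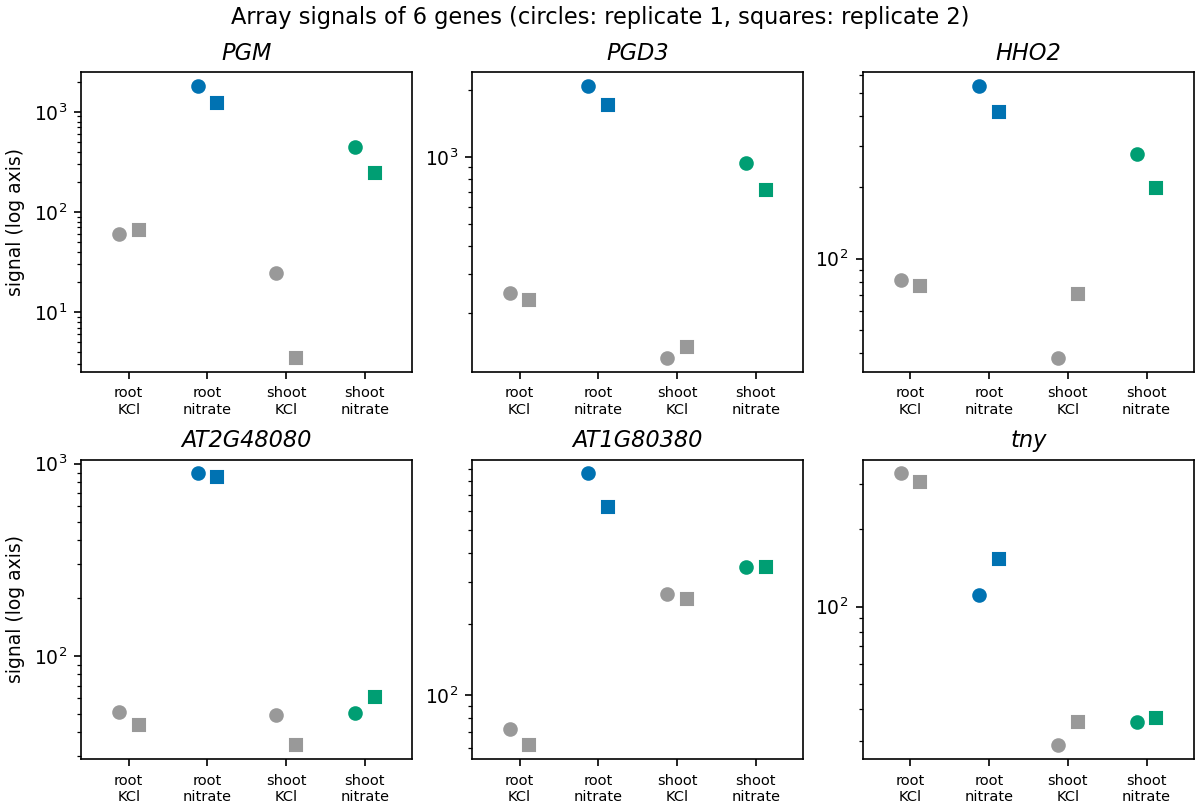
Signal on each array (log axis) of 6 genes, with groups along the x axis, circles for replicate 1 and squares for replicate 2. PGM, PGD3 and HHO2 were higher with nitrate in both organs on both arrays, though HHO2 did not pass the test in shoots, whereas AT2G48080 rose in roots from 47.2 to 872 and stood at 41.5 and 55.7 in shoots.

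The gene lists fixed in advance could be tested only in part, because the probe table names 27 of their 220 genes and 23 were tested. The table lists no probe set for nitrate reductase, nitrite reductase or the nitrate transporters NRT1.1 and NRT2.1, so these were not analysed here by name; probe sets without a listed gene were tested unnamed. In the pentose phosphate list of 23 genes, 2 of 3 tested genes rose in roots, PGD3 and PGD1. PGD2 had a log2 change of 0.06 ± 0.19 (SE). In the list of 29 nitrate regulators, 2 of 3 tested genes rose, HHO2 and HHO3. HHO2 and HHO3 missed the threshold under 3 and 4 of 21 alternatives, and NRG2 had a log2 change of 0.14 ± 0.18. In the list of nitrate and nitrite reduction 1 of 2 rose, CNX6 (AT2G43760), of molybdenum cofactor synthesis, by 1.47 ± 0.21 (limma, adjusted p = 0.0134; missed under 5 of 21 alternatives, where it was up to 0.21), and SIRB had -0.05 ± 0.17. The counts adjusted over the list alone were the same for these 3 lists.

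By camera with a preset correlation, 5 of 14 lists were called in roots: pentose phosphate (adjusted p = 2.93e-08), nitrate regulators (1.43e-07), nitrate and nitrite reduction (0.0209), sulfate assimilation (0.0209) and, lower with nitrate, auxin early response (0.0413). None was called with an estimated correlation: the adjusted p was 0.095 for each of the first 2, 0.177 for reduction, 0.177 for sulfate and 0.197 for auxin. These p are adjusted over 14 lists, 8 of them with 1 tested gene; adjusted over the 3 lists with at least 3 tested genes, a choice made after the coverage was known, the first 2 had an adjusted p = 0.0204 with an estimated correlation. With the preset correlation, 2 lists were called without the second root KCl array and 3 without the first root nitrate array. The estimated correlation was -0.18 for reduction and -0.04 for auxin, and none could be estimated for sulfate. A positive correlation between genes therefore does not account for the loss of these calls in that setting. The sulfate list had 1 tested gene, SIR (log2 change of 0.55 ± 0.16). It passed only at an unadjusted p, since adjusting over 1 gene changes nothing, and not over all probe sets (limma, adjusted p = 0.337). The auxin list had 2, GH3.3 (-0.53 ± 0.23) and LBD16 (-0.34 ± 0.18), and neither passed. The 9 lists not called had adjusted p of 0.601 (nitrate transport), 0.876 (organic acid supply), 0.173 (cytokinin), 0.631 (sugar starvation), 0.752 (circadian clock), 0.877 (touch, cold and wounding), 0.226 (heat shock), 0.631 (photosynthesis) and 0.877 (root cell markers).

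Nitrate against KCl in shoots asked for the same response in the other organ. In the planned fit 13 probe sets rose in shoots and none passed as a fall by limma, with 323 at an unadjusted p under 0.05. With a replicate block within each organ 78 rose and 4 fell, and with a block shared by both organs 36 rose. The named ones among the 13 were 5 probe sets of 4 genes. PGM rose by 3.61 ± 0.39 on the log2 scale (SE; limma, adjusted p = 0.015), from a signal of 14.1 ± 15.1 to 343 ± 139. PGD3 rose by 2.49 ± 0.19 (adjusted p = 0.00303), from 133 ± 10.6 to 828 ± 158. AT4G36010 rose by 2.28 ± 0.20 (adjusted p = 0.00461), and both probe sets of AT5G54130 rose, one by 2.32 ± 0.20 (adjusted p = 0.00461) and the other to a signal of 168 ± 72.2 (adjusted p = 0.0329). PGM missed the threshold under 5 of 21 alternatives, and the second probe set of AT5G54130 under 8. None of these 5 named probe sets passed with only the shoot arrays in the fit. The largest rise, by 4.54 ± 0.19, was of a probe set with no gene in the table, from 45.3 ± 6.99 to 1425 ± 291.

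HHO2 and HHO3 had log2 changes of 1.87 ± 0.26 and 1.83 ± 0.26 in shoots (SE; limma, adjusted p = 0.0617 for both), so 0 of 3 nitrate regulators passed over all probe sets and 2 passed adjusted over the list alone. PGD1 had 1.54 ± 0.26 (adjusted p = 0.162), so 1 of 3 pentose phosphate genes passed over all probe sets and 2 over the list alone. The lowest p among falls belonged to AT3G19680 (-0.82 ± 0.19), AT5G56980 (-0.84 ± 0.21), AT5G41950 (-0.62 ± 0.15), AT2G29660 (-0.62 ± 0.16) and AT2G37580 (-1.15 ± 0.30), none of which passed. By camera with a preset correlation 3 lists were called: pentose phosphate (adjusted p = 1.81e-07), nitrate regulators (5.4e-06) and nitrate and nitrite reduction (0.0417). None was called with an estimated correlation, where the adjusted p was 0.113, 0.113 and 0.272. Over the 3 lists with at least 3 tested genes the adjusted p was 0.0242 for each of the first 2. For reduction the estimated correlation was -0.18, so a positive correlation does not account for the loss of that call. The other lists had adjusted p between 0.68 and 0.991, and for the root cell markers the median log2 change (-0.06) differed in sign from the mean (0.04) and the test.

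The fit shared 1 spread between organs although the shoot samples differed more: with only the shoot arrays in the fit 1 probe set was called, and a single draw of simulated arrays with a spread per organ gave 40 false calls among 200 in shoots against 2 among 171 in roots. With a shift shared by arrays of the same number added, no call was false among 98 in shoots, and 9% of 2-fold changes were recovered there. The count was 8 without the first KCl array and 25 without the second.

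The response of roots minus that of shoots asked whether the organs differ, which separate calls cannot show. In the planned fit the difference itself passed for 2 genes: AT2G48080, with 3.49 ± 0.26 on the log2 scale (SE; limma, adjusted p = 0.00976), and AT1G80380, with 2.79 ± 0.26 (adjusted p = 0.0284). AT1G80380 rose in roots from a signal of 66.8 ± 7.67 to 745 ± 170 and stood at 261 ± 10.4 and 348 ± 0.12 in shoots. At an unadjusted p under 0.05 there were 355 probe sets, and at a pseudocount of 64 the test called 20. With a replicate block it called 6 when the block was shared by both organs. It called 80 (67 higher, 13 lower) with a block within each organ, though the labels do not say what the number marks. AT1G80380 missed the threshold with any 1 of the 8 arrays left out (limma, adjusted p from 0.0718 to 0.334), and AT2G48080 with any of the 4 root arrays or the first shoot nitrate array left out (0.0519 to 0.164), while both differences stayed at or above 2.56.

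All 13 probe sets called in shoots were also called in roots in the same direction, where independent lists of these sizes would share 0.134. Both comparisons used the same estimate of spread per probe set, so the 2 lists are not independent and 0.134 is only a reference. The overlap depended on the fit. It was 1 with each organ fitted alone, 34 with a replicate block shared by both organs and 67 with a block within each organ. Of the 141 that rose in roots, 135 had a positive change in shoots and 82 of these an unadjusted p under 0.05. Their median log2 change was 1.84 in roots and 0.56 in shoots, and 138 were larger in roots, the organ they were chosen in. Across all tested probe sets, which are not independent replicates, the changes of the 2 organs had a Pearson correlation of 0.438 and a Spearman correlation of 0.161.

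**Figure D3:**
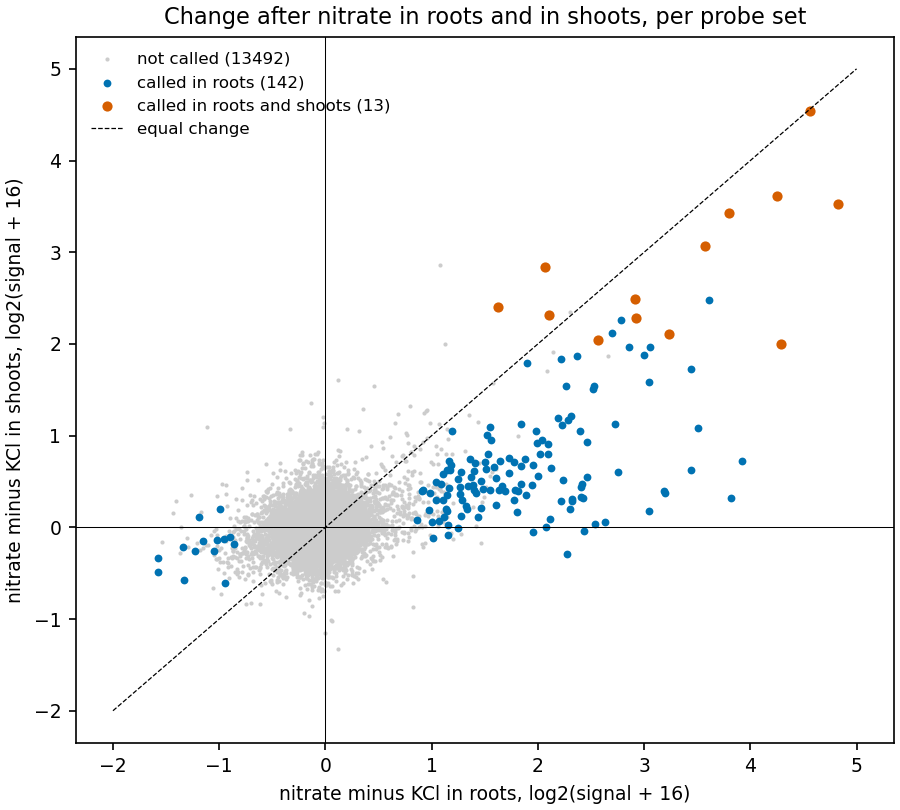
Change after nitrate in roots (x axis) and in shoots (y axis) per probe set, both on the log2(signal + 16) scale, with 13492 probe sets not called in grey, 142 called in roots alone in blue and 13 called in both organs in orange. The dashed line marks equal change, and most blue points lie below it.

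Roots against shoots in KCl gave the baseline difference between the organs and checked their labels. In KCl roots were higher for 2534 probe sets and lower for 2619 of 13647 (limma, adjusted p under 0.05). RCA, which encodes Rubisco activase of green tissue, had a signal of 143 ± 39.7 in roots and 3343 ± 1203 in shoots. The root hair expansins EXPA7 and EXPA18 stood at 153 ± 32.7 and 260 ± 33.0 in roots against 17.0 ± 11.9 and 18.6 ± 23.4 in shoots. PYK10, a beta-glucosidase listed as a root marker, did not separate the organs, with 3405 ± 455 and 2734 ± 679 (limma, adjusted p = 0.304).

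The named genes with the largest log2 values on the root side were AT3G01190, a peroxidase, by 5.30 ± 0.38 on the log2 scale (SE; limma, adjusted p = 1.57e-05), AT3G45710 (5.04), AT1G14960 (4.84), AT2G21045 (4.75) and AT4G26010 (4.75), another peroxidase. On the shoot side they were AT1G09310 (-6.21), ECS1 (-6.15), AT2G10940 (-5.93), AT1G23130 (-5.74) and AT3G16530 (-5.51). All 10 passed under every alternative run for this comparison, but the 5 on the shoot side had root signals under the filter value of 33.3, and the sizes depended on the pseudocount. AT3G16530, at 10.4 ± 11.1 in roots, ran from -7.11 to -4.02 and AT3G01190, at 12.5 ± 11.3 in shoots, from 3.89 to 6.61. Requiring a 2-fold change as well left 3404 probe sets for roots versus shoots in KCl.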

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

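The tests on replicate numbers were chosen after their results were seen, and the bound against lower RNA integrity was loosened, from 3 or fewer of 5 control pairs to none, after its value was known. The tests on the number of calls were set before, except for how many probe sets to choose: 50 was run first, and 25, 100 and 200 were then added.

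In the planned fit the response to nitrate differed between organs for AT2G48080, by 3.49 on the log2 scale, and for AT1G80380, by 2.79. This is by the test of the difference itself. The threshold was missed by AT2G48080 under 5 of 21 alternatives and by AT1G80380 under 9. Both rose in roots.

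Fewer probe sets passed in shoots (13) than in roots (155). Lower precision of the shoot arrays alone would leave the changes as large as in roots. Among probe sets chosen by the root arrays numbered 1, the median shoot change was 0.596 of that in the root arrays numbered 2 at the choice of 25 (bootstrap interval 0.355 to 0.705). It was lower at the other choices. The bootstrap intervals given here resampled probe sets, not samples, so they leave out the spread between arrays. Transcripts chosen in roots thus changed less in shoots, but choosing them for a rise in roots favours this. The ratio therefore cannot decide why fewer probe sets passed in shoots, since shoots could respond through other transcripts. In the planned fit, however, each probe set had 1 SE shared by both organs (median 0.214). A larger SE in shoots thus does not account for their lower count in that fit. Among probe sets chosen by the shoot arrays numbered 1, the ratio was 0.627 (0.541 to 0.746) for 50, the first size run, and 0.606 (0.53 to 0.829) for 25, 0.693 (0.475 to 0.935) for 100 and 1.47 (0.62 to 2.37) for 200, where the median changes were only 0.29 and 0.20. The first size alone met the prediction of a smaller change in shoots of the transcripts chosen there, and the sizes added later leave it open, as does a difference between the organs in biology, which was not tested further.

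Plastid-encoded transcripts and ICL differed between arrays numbered 1 and 2. Less green tissue in the shoot arrays numbered 1 would lower nuclear shoot transcripts alike. The median difference (number 2 minus number 1, log2) of 140 such transcripts was -0.19 against 0.47 for 60 plastid-encoded ones. This shows only that the nuclear ones as a set were not lower on the arrays numbered 1. A like change of both kinds was assumed, yet plastid-encoded transcripts did not all move together in shoots (psbA -2.53, rbcL 2.17). Shoot RNA in the root arrays numbered 2 would add the same percent of the shoot signal to both kinds. The plastid median was 10.3% against 0.318% for the nuclear ones, whose 95th percentile was 3.42%. However, the 140 nuclear transcripts were chosen as at least 16-fold higher in shoots than in roots over all arrays. That choice includes the root arrays numbered 2 and limits the signal these transcripts could gain, while the plastid-encoded ones had no such limit. The comparison therefore cannot decide this explanation. Lower RNA integrity in the shoot arrays numbered 1 could not be decided: 2 of 5 control pairs, both actin, had a higher 3'/5' ratio on both of these arrays, and GAPDH and ubiquitin did not. No biological explanation was tested, since the labels give none for the number.

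Fewer probe sets fell than rose in roots. If the pseudocount and the filter hid falls, removing them would raise the share of falls. With a pseudocount of 1 and no filter 3.81% of calls fell (4 of 105). That setting also called fewer rises, 101 against 141 in the planned fit. It may have missed falls as well, so it cannot decide whether falls were hidden. The share of falls varied with the fit, to 56 of 279 calls with only the root arrays. It was 195 of 517 with a replicate block within each organ, so the size of the shortage stays open.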

How the results depend on the processing

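The alternatives without both shoot arrays numbered 1, without plastid-encoded genes, with a pseudocount of 1 and no filter together, and with lists of at least 3 tested genes, by either correlation, were chosen after the data were seen. All 58 called results of named genes or probe sets kept their sign under every alternative, and 21 of them stayed past the threshold throughout. Of 2117 values of named results under an alternative, 1864 kept sign and side, 198 lost the call, 15 gained one and 40, all of uncalled genes, reversed. The number of arrays limits the precision.

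Counts moved more than 1.5 times as follows; where fewer samples or a stricter threshold does not show it, the cause was not tested. Roots had 279 calls with only the root arrays, 273 (219 higher, 54 lower) without both shoot arrays numbered 1 and 83 at an adjusted p under 0.01; shoots had 1 with only the shoot arrays and 6 at 0.01. The difference between organs had 20 calls at a pseudocount of 64 and 1 at 0.01, the overlap was 1 with only each organ's arrays, and roots versus shoots in KCl had 3404 at a 2-fold change. Lists called in roots were 2 with at least 3 tested genes, also with an estimated correlation, and with all lists, in roots and shoots alike 0 with an estimated correlation, 0 by fry's mixed test and 0 by camera on ranks; fry's direction test called 5 in roots and 2 in shoots. With 1 array left out, which assumes that the lone sample varies like the other groups, counts were 32 to 58 in roots, 8 to 25 in shoots, 0 to 1 for the difference, 6 to 19 for the overlap, and 2 to 5 lists in roots.

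Arrays of the same replicate number deviated together, with correlations from 0.207 to 0.665, a hint from the data that they share something; the labels do not say that a number marks a shared culture or day, so they were not treated as pairs. With a replicate block shared by both organs there were 264 calls in roots, 36 in shoots, 6 for the difference and 34 in the overlap. With a replicate block within each organ there were 517 (322 higher, 195 lower), 82 (78 higher, 4 lower), 80 (67 higher, 13 lower) and 67. The share of falls in roots, and not only the number of calls, thus depended on the block.

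Reversed log2 changes, none of a called gene and their cause not tested, were as follows. With quantile normalization between the 8 arrays and within each organ, cICDH in roots had -0.0120 and -0.00653, and RCA in shoots 0.00379 and 0.00482. Without both shoot arrays numbered 1, shoots had GH3.3 -0.0358, LBD16 -0.11, GI 0.0697, EXPA18 -0.28, EXPA7 0.39, NRT1.4 (AT2G26690) -0.13, RCA 0.0216 and AKINBETA1 -0.14. With 1 array left out, ranges in roots were -0.71 to 0.32 (ZAT10, also STZ), -0.16 to 0.11 (PYK10), -0.38 to 0.0229 (EXPA7), -0.00697 to 0.0754 (cICDH), -0.50 to 0.0110 (RCA), -0.40 to 0.12 (GI) and -1.25 to 0.34 (NRT2.5). In shoots they were -0.0533 to 0.14 (LBD16), -0.24 to 1.26 (EXPA18), -0.72 to 0.0285 (EXPA7), -0.31 to 0.49 (NRT1.4), -0.61 to 0.13 (RCA), -1.15 to 0.86 (ZAT10), -0.0693 to 0.19 (GH3.3), -0.22 to 0.11 (GI), -0.13 to 0.46 (HSP22), -0.23 to 1.33 (NRT2.5), -0.13 to 0.13 (cICDH), -0.00858 to 0.39 (AKINBETA1) and -0.0739 to 0.23 (SIR).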

Other observations

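The genes and searches in this part were chosen after their values were seen. Of the transcripts that rose in roots, 6 more are named. AT5G62720 and AT3G47980, HPP-family membrane proteins of the kind known for plastid nitrite transport, rose by 1.88 ± 0.18 and 1.84 ± 0.23 on the log2 scale (SE; limma, adjusted p = 0.0021 and 0.00602). MDH, a malate dehydrogenase, rose from a signal of 468 ± 29.1 to 1376 ± 239 (adjusted p = 0.00501). AT1G22170, a phosphoglycerate mutase family member like PGM, rose by 1.77 ± 0.19 (adjusted p = 0.00358). HYH, a bZIP transcription factor close to HY5, rose by 2.23 ± 0.37 (adjusted p = 0.029; missed under 8 of 21 alternatives, where it was up to 0.32), and AT5G51830, a fructokinase, by 2.41 ± 0.25 (adjusted p = 0.00326). The threshold was missed by AT3G47980 under 4 of 20 alternatives, by MDH and AT1G22170 under 3 of 21, and by AT5G62720 and AT5G51830 under 1. In shoots MDH had a log2 change of 1.00 ± 0.18 (limma, adjusted p = 0.219), and the other 5 had larger p.

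Other transcripts followed the replicate number in shoots. With the number as a term in the fit, 3638 probe sets differed between numbers in shoots and 103 in roots. AT1G47400, a gene of the IRON MAN peptides induced by iron shortage, had signals of 315 and 433 on the shoot arrays numbered 1 and 15.1 and 16.6 on those numbered 2. Of 60 plastid-encoded probe sets, 28 passed as higher and 2 as lower on the arrays numbered 2 in shoots, and 16 as higher and none as lower in roots (limma). The difference was positive for 54 in shoots and 59 in roots, whether or not it passed, while psbA was higher on the shoot arrays numbered 1 (1878 and 1726 against 351 and 254).

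In a search over groups of genes, 31 groups (families of gene symbols with at least 5 tested members, and the plastid-encoded genes) were tested with camera, and none passed for nitrate in roots (lowest adjusted p = 0.256) or in shoots (0.507). At an unadjusted p under 0.05 there were 4 in roots and 1 in shoots.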
